A study of Caenorhabditis elegans with 4 samples.

How the data were processed

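Binding of the transcription factor LSY-2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in *Caenorhabditis elegans* hermaphrodites at the L4 larval stage. In the strain, OP240, an lsy-2 transgene carries EGFP and FLAG tags in an unc-119 background. Per the labels' protocols, worms were grown at 20 degrees, crosslinked with formaldehyde and sonicated, and the tagged protein was collected with a goat antibody to GFP. The study holds 4 samples: 2 LSY-2 ChIP libraries and 2 input libraries of total chromatin, each numbered 1 and 2 in the labels. The input libraries were not analysed here. Nothing in the labels says whether the numbered libraries came from separate cultures, so p-values measure only these libraries and agreement between them may be technical.

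The files were 3 peak lists: 1 for each ChIP library and 1 for the whole series. Per the file headers, coordinates follow WormBase build WS180. The source column of each list names the peak caller PeakSeq, which scores regions of ChIP reads against a control. The aligner, software versions, read filters, threshold and the way in which the series-wide list was made are not given in the sources used here. Each row holds an interval and the q value that the authors' peak caller gave it, and the deposited q value is repeated in the attribute column of every row (884, 1033 and 1910 rows). The highest q values listed were 0.000148, 0.000159 and 0.000195. No read counts, folds or heights were in the lists, so the depth of the libraries is unknown, and a q value mixes enrichment with depth. Nothing says that the lists share a scale of q values. Agreement between replicates was therefore tested on ranks, and differences or ratios of −log10 q between lists are descriptions that assume a shared scale. Coordinates are printed 1-based, as in the files.

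Peaks of both replicates that overlapped by at least 1 bp were merged, and merged intervals that held a peak of each replicate are called consensus regions. Overlap between replicates was compared with 1000 random placements of a replicate's peaks inside their own chromosomes (one-sided; the smallest p possible is 0.001). Values of −log10 q were compared over overlapping pairs with Spearman's rho. That test and the differences of medians used permutation with 100000 resamples, two-sided (the smallest p possible is 1e-05). Shares are given with exact Clopper-Pearson 95% intervals, which treat peaks as independent and cover counting error only. Chromosome shares were tested with the two-sided exact binomial test and compared with Fisher's exact test, with Benjamini-Hochberg adjustment over the 6 chromosomes where all were tested. The WS180 chromosome lengths were not used here. The end of the last peak in any of the 3 lists stood for each chromosome's length, and the central part is the middle 50% of that span. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

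The overlap and location counts were tested on simulated data. In 20 pairs of lists with 800 peaks each and 500 planted shared peaks, between 500 and 509 were found. Planted peaks were shifted by less than their width, so they had to overlap, and this checks the counting only. Of 20 unrelated pairs, 0 had a placement p under 0.05. The moved list of each unrelated pair was placed evenly, like the random placements, so the effect of clustered peaks was not tested. A planted central share of 65% was found as 65.1% ± 2.28 (SD over the 20 pairs).

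The rule for named regions, the tests and the alternatives were fixed before the data were examined, with the exceptions given here. The rule names the 20 consensus regions with the best mean rank of −log10 q over both replicates. It also asked for the genes beside them, for lsy-2, lsy-6 and unc-119, and for bound members of 18 gene lists. The gene table at hand follows another build (WBcel235), and coordinates of different builds were not combined. Genomic location, gene list, non-coding RNA class and sequence word analyses were therefore not run, and regions are named by position. Alternatives that were tried are stricter overlap, the better-ranked 50% or the best 200 peaks of each list, each replicate alone, the series-wide list in place of the consensus regions, another chromosome span, and permutation of 1 Mb bins. The last 2 of these were chosen after seeing the data, as were Fisher's exact tests, the tests of single chromosomes other than X and the tests of why patterns arose, except that of the better-ranked 50% of the consensus regions, which was planned.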

Results

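LSY-2 is a zinc finger transcription factor known for its part in the left-right asymmetry of the ASE taste neurons, where it acts upstream of the microRNA lsy-6. Its binding was mapped here in whole L4 larvae through a GFP-tagged transgene. Replicate 1 listed 884 peaks with a median width of 644.5 bp (quartiles 448 and 934) that covered 0.705 Mb. Replicate 2 listed 1033 peaks with a median width of 667 bp (quartiles 449 and 943) that covered 0.844 Mb. The series-wide list held 1910 peaks with a median width of 624 bp (quartiles 418 and 948) that covered 1.56 Mb. The median −log10 q was 7.60 in replicate 1, 7.31 in replicate 2 and 7.33 in the series-wide list, and in each list about 36.4%, 36.3% and 36.3% of peaks, in that order, had a q below 1e-10. The depth of the libraries is unknown. All positions are in build WS180.

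The first comparison asked which regions both ChIP libraries held. Their peaks formed 752 consensus regions, which spanned 0.769 Mb and had a median width of 810.5 bp (quartiles 585 and 1186). Of these, 728 came from 1 peak of each replicate. The samples include no untagged control, so LSY-2 binding was not told apart from sequence that the procedure enriches without it. In replicate 1, 773 of 884 peaks were overlapped by a peak of replicate 2, a share of 87.4% (95% interval 85.1 to 89.6). In replicate 2, 765 of 1033 peaks were overlapped, a share of 74.1% (71.3 to 76.7). Random placement overlapped 1.70% and 1.44% on average, and at most 3.17% and 2.61% (permutation p = 0.001 for both, the smallest the placements can give). The placements spread peaks evenly along each chromosome and take no account of mappability or clustering. The p therefore says only that the overlap exceeds an even spread, and the shares themselves describe the agreement.

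The 20 best-ranked regions lay on all 6 chromosomes, with 6 each on III and IV, 3 on II, 2 each on I and X, and 1 on V. They were broad: the median width was 2210 bp (range 1148 to 3828), against 797 bp for the other 732. The strongest region was chromosome IV 4747547 to 4751374, with a −log10 q of 265 in replicate 1 and 289 in replicate 2. The next was chromosome III 3866012 to 3868762, with 221 and 274. It was followed by chromosome V 11763199 to 11765972, with 211 and 235, and by chromosome IV 653279 to 655635, with 192 and 214. Chromosome III held another pair of regions of this strength. At 4474394 to 4476989 the −log10 q was 179 and 190, and at 12904088 to 12907209 it was 162 and 208.

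On the X chromosome, the region at 15840377 to 15842802 had a −log10 q of 155 in replicate 1 and 163 in replicate 2, and the region at 16929260 to 16931956 had 145 and 187. The remaining regions of chromosome III among the 20 lay at 9764613 to 9766647 (130 and 174), 8903542 to 8905596 (96.2 and 105) and 13462397 to 13465799 (89.7 and 119.2). Those of chromosome IV lay at 3049543 to 3051820 (134 and 146), 1093502 to 1095088 (127 and 137), 8431515 to 8433655 (95.3 and 124) and 4724721 to 4726005 (78.3 and 97.5). On chromosome I, the regions at 9619036 to 9620888 and 9787524 to 9789575 reached 123 and 107 in replicate 1 and 149 and 133 in replicate 2. On chromosome II, the regions at 10867955 to 10869709, 3076606 to 3077753 and 8184441 to 8185887 reached 122, 103 and 102 in replicate 1 and 132, 116 and 122 in replicate 2. The genes beside these regions were not analysed here.

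The strength of the regions ranked alike in both libraries. Over 786 overlapping pairs of peaks, Spearman's rho of −log10 q was 0.84 (permutation p = 1e-05, the smallest the resamples can give). This is a relation across peaks of 1 pair of libraries, and peaks are not independent replicates. Replicate 2 had the lower q in 525 of the 786 pairs (66.8%) and in all 20 of the best-ranked regions. The median difference was 1.49 units of −log10 q (quartiles −0.56 and 4.28). With 1 library on each side and no depths, this difference between libraries was not tested.

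**Figure D1:**
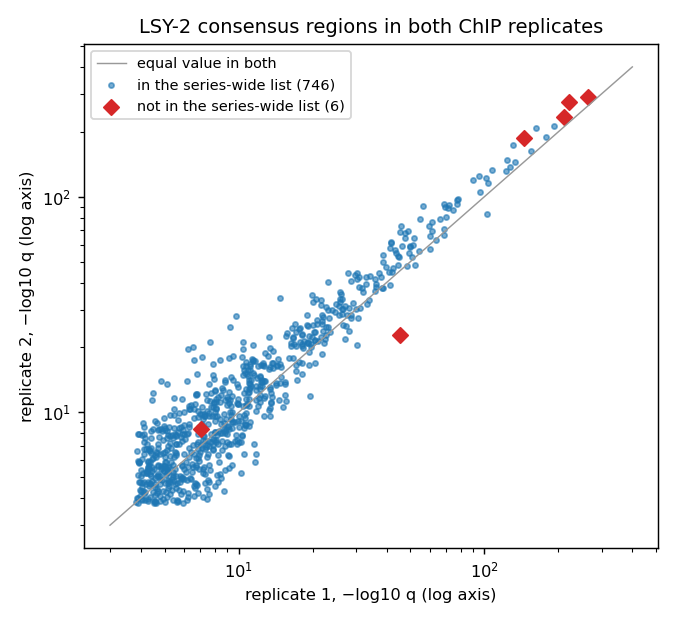
Each point is 1 of the 752 consensus regions, with −log10 q of replicate 1 on the x axis and of replicate 2 on the y axis, both on log axes; the line marks equal values. The red diamonds are the 6 regions with no peak in the series-wide list, and 4 of them are among the 20 best-ranked.

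Peaks found in only 1 library were weaker and narrower than shared peaks. The best 200 peaks of each replicate were all overlapped by peaks of the other's whole list (200 of 200, lower 95% bound 98.2%). For ranks 601 to 800 the share was 73.5% (66.8 to 79.5) in replicate 1 and 60.5% (53.4 to 67.3) in replicate 2, and for ranks 801 to 1000 of replicate 2 it was 31% (24.7 to 37.9). In replicate 1 the 773 shared peaks had a median −log10 q of 8.51, against 4.41 for the 111 unshared peaks (permutation p = 2.0e-05). Their median widths were 679 and 420 bp (permutation p = 1e-05). In replicate 2 the 765 shared peaks had a median −log10 q of 9.72, against 4.53 for the 268 unshared peaks, and median widths of 733 and 468 bp (permutation p = 1e-05 for both). Peaks near a list's threshold and narrow peaks are more easily left without overlap. These differences therefore describe the lists and say nothing more about binding.

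**Figure D2:**
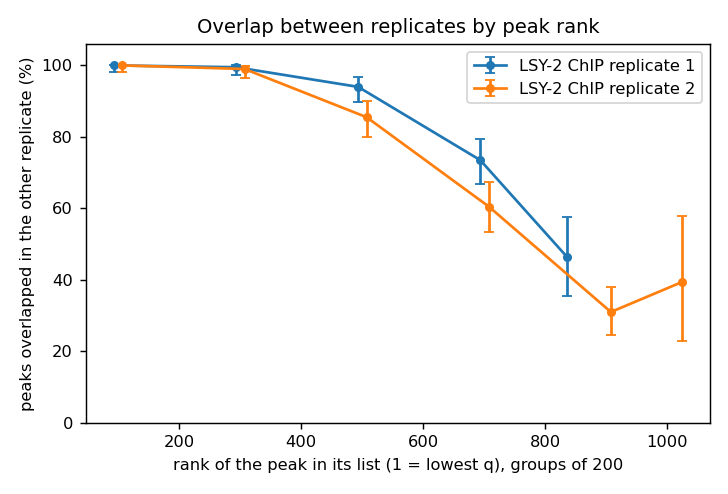
The x axis is the rank of a peak in its own list, in groups of 200 from the lowest q, and the y axis is the percentage of the group overlapped by a peak of the other replicate, with exact 95% intervals as bars. The share is 100% in the best 200 of both replicates and 46.4% and 39.4% in their last groups, which hold 84 and 33 peaks, with the lowest value, 31%, at ranks 801 to 1000 of replicate 2.

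The series-wide list was compared with the replicate lists to see which regions it added or lacked. It was not a concatenation of them: 0 of its intervals were identical to one of replicate 1, and 1 to one of replicate 2. Of its 1910 peaks, 730 (38.2%) overlapped peaks of both replicates, 5.45% of replicate 1 only and 247 (12.9%) of replicate 2 only. The other 829 (43.4%, 95% interval 41.2 to 45.7) overlapped none. These 829 peaks had a median −log10 q of 4.81 (quartiles 4.14 and 5.91) and a median width of 456 bp, against 18.7 and 906.5 bp for the 730 peaks found in both. In the opposite direction, 875 replicate 1 peaks (99%) and 1014 replicate 2 peaks (98.2%) overlapped the series-wide list.

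Chromosome I held 167 of the 829 series-wide peaks without a replicate peak (20.1%), against 13.2% of the peaks with one (Fisher's exact p = 5.9e-05, adjusted 0.00035). Chromosome III showed the opposite, with 15.1% against 20.1% (Fisher's exact p = 0.0047, adjusted 0.014). On II, IV, V and X the difference did not pass the test (adjusted p of Fisher's exact test from 0.58 to 1). The permutation test over all 6 chromosomes together gave p = 0.00055. These tests were not planned before the data were examined, and they take peaks as independent. Several consensus regions of chromosome I had a higher series-wide −log10 q than regions elsewhere that were of like strength in the replicates. Whether the series-wide list scored all chromosomes alike was not tested, so the differences describe the lists and not where LSY-2 bound.

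The series-wide list lacked 6 consensus regions. Among them were 4 of the 7 best-ranked: chromosome IV 4747547 to 4751374, chromosome III 3866012 to 3868762, chromosome V 11763199 to 11765972 and chromosome X 16929260 to 16931956. The other absent regions were on chromosomes I and III. Chromosome I 15063998 to 15067639, the last listed interval of its chromosome, had a −log10 q of 45.5 in replicate 1 and 22.8 in replicate 2. Chromosome III 3868957 to 3870006 had 7.0 and 8.36. The replicate peaks that were in 1 library only and absent from the series-wide list, 3 of replicate 1 and 13 of replicate 2, had −log10 q of 4.66 or less. The lowest q of the series-wide list belonged to chromosome V, where the consensus region at 6220862 to 6230086, the widest of all at 9225 bp, had a −log10 q of 102 in replicate 1, 82.8 in replicate 2 and 274 in the series-wide list.

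The last comparison asked how LSY-2 regions were spread over the chromosomes. The X chromosome held 140 of the 752 regions, a share of 18.6% (95% interval 15.9 to 21.6), where its span is 17.6% of the total. The difference did not pass the exact binomial test (p = 0.473). When the other chromosomes were examined as well, a step chosen afterwards, chromosome III had the highest density with 11 regions per Mb (95% interval 9.36 to 12.9) and chromosome V the lowest with 5.28 (4.34 to 6.36). Both differed from an even spread (exact binomial test, adjusted p = 7.8e-06 and 4.7e-05). That test takes regions as independent. Chromosome III was also tested in 1 Mb bins, as given below, but V was not. Chromosomes I, II and IV had 6.64, 7.34 and 7.90 regions per Mb and X had 7.94, and none of the 4 passed (adjusted p of the exact binomial test 0.37 or more). III had the highest and V the lowest density in each replicate's list and in the series-wide list too, with 13.2 and 6.24 peaks per Mb in replicate 1, 14.8 and 7.44 in replicate 2, and 24.8 and 13.2 in the series-wide list.

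On the autosomes the regions were concentrated in the middle of the chromosomes. The central part, the middle 50% of each chromosome, held 383 of 612 autosomal regions, or 62.6% (95% interval 58.6 to 66.4; exact binomial p = 5.1e-10 against 50%). On the X chromosome it held 64 of 140, or 45.7% (37.3 to 54.3; exact binomial p = 0.353). With regions taken as independent, the central shares of X and autosomes differed (Fisher's exact p = 0.000285). Among the autosomes the central share was 68.2% on V, 66.4% on III, 63% on I, 62.5% on II and 53.6% on IV. The interval for IV (44.9 to 62.1) included 50% and overlapped that of X. Neighbouring regions are not independent. Bins of 1 Mb were therefore compared too. They were the whole Mb of each span, so the last partial Mb of each chromosome, which is outer, was left out with its regions. In these bins, the autosomal centres held 9.22 ± 4.29 regions per Mb (SD, n = 41 bins) and the outer parts 5.51 ± 3.72 (n = 39; permutation p = 9.0e-05). By the same test chromosome III held 11.1 ± 5.39 regions per Mb (n = 13) against 6.94 ± 3.70 elsewhere (n = 84; permutation p = 0.00092). III already had the highest density of the 6 chromosomes, and this p is not adjusted for that choice. The permutations also treat neighbouring bins of 1 chromosome as independent, so the p may be too small. The X centre held 7.89 regions per Mb and its outer parts 7.88. The difference in central share between X and autosomes was not tested in bins.

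**Figure D3:**
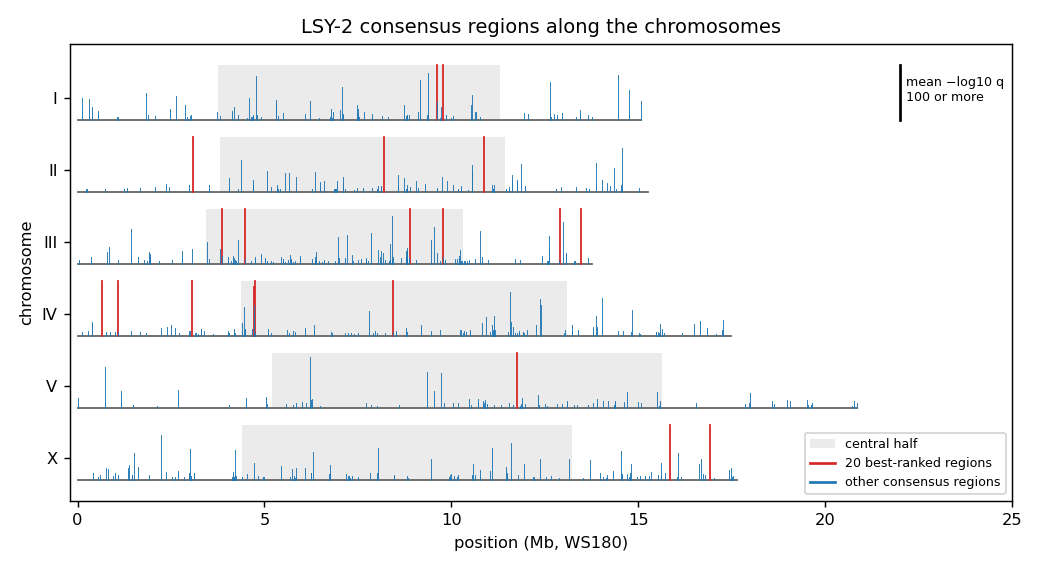
Each vertical line is 1 of the 752 consensus regions at its WS180 position in Mb (x axis) on chromosomes I to X; its height is the mean −log10 q of both replicates, drawn up to 100, and the grey band is the middle 50% of the chromosome. The 20 best-ranked regions, in red, lie on all 6 chromosomes, with 6 each on III and IV.

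**Figure D4:**
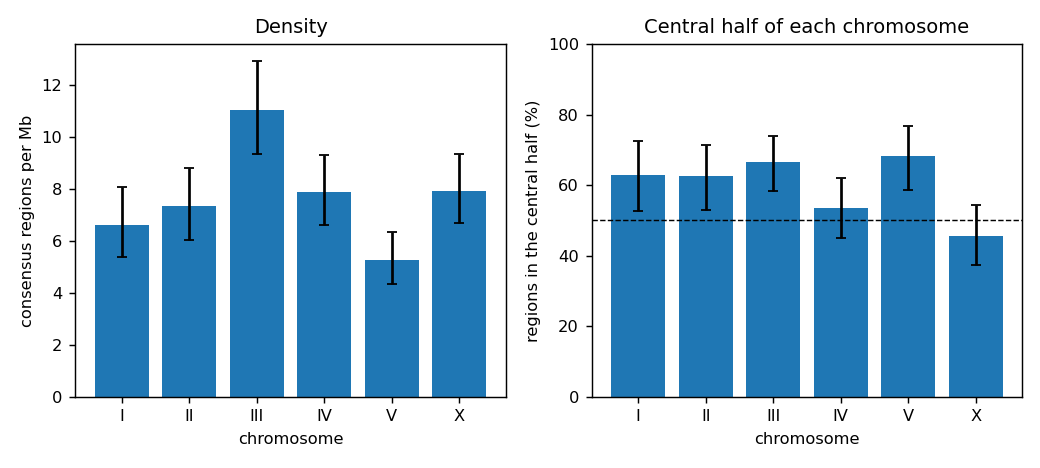
The left plot gives consensus regions per Mb of each chromosome (bars, with exact Poisson 95% intervals), highest on III (11) and lowest on V (5.28). The right plot gives the percentage of a chromosome's regions in its middle 50% (bars, with exact 95% intervals), which lies above the dashed 50% line on I, II, III, IV and V and below it on X (45.7%).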

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

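For the 10 results that answer a comparison, 34 of 35 alternatives kept the direction and the side of the threshold. A shared percentage cannot be negative, so the overlap results could not change direction. For the X results, keeping the side means only that no p fell under 0.05. Under stricter overlap, the better-ranked 50% or the best 200 peaks, the shared percentage ranged from 74.0 to 92.1 in replicate 1 and from 63.3 to 92.0 in replicate 2. Spearman's rho was 0.89 with reciprocal overlap of at least 50% and 0.87 in the better-ranked 50% of peaks, the alternatives run for it. The autosomal central share was 62.3% with replicate 1 alone, 63.6% with replicate 2 alone and 61% with the series-wide list. The exception is the central share of X regions, in 1 Mb bins, a test chosen after seeing the data. There the X centre held 7.89 regions per Mb and the outer parts 7.88 (permutation p = 1), so the sign reversed between values that are both far from passing. The 17 whole bins leave out the outer end of the 17.6 Mb span of X, and their 9 central bins have other edges than its middle 50%. The 2 measures thus divide X differently, and the reversal says nothing about binding. A ranking by q instead of a score gave no further value, because the lists' score column is the q value. Placement within promoters and all alternatives that need genes or sequence were not run. No paired analysis was possible because no lists of the input libraries, which share the numbers 1 and 2 with the ChIP libraries, were used here, so no groups were compared. The lists give no read counts, so absence from a list says only that a peak did not reach that list's threshold at an unknown depth.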

Other observations

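The test of the central share in the better-ranked 50% of the regions was planned before the data were examined. The other tests were added later: those of joined and of close regions before their own results were seen, and those of the regions absent from the series-wide list and of single autosomes after.

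LSY-2 regions often lay in small groups. Of the 752 consensus regions, 265 (35.2%) had their midpoint within 10000 bp of another region's midpoint. Of the groups these formed, 82 held 2 regions, 21 held 3, 7 held 4 and 2 held 5. The groups of 5 lay on chromosome II from 10541928 to 10563902 and on chromosome III from 3854776 to 3870006. The chromosome III group includes the second best-ranked region. Of the 9 groups with 4 or 5 regions, 5 were on chromosome III, 2 on II and 2 on V. Some regions were wide: 18 were 3000 bp or more, and across regions width rose with strength (Spearman's rho 0.55; regions are not independent replicates). After the 9225 bp region on chromosome V, the widest was chromosome I 7079167 to 7084986, at 5820 bp, with a −log10 q of 45.7 in replicate 1 and 72.9 in replicate 2.

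Random positions inside the same 1 Mb bins gave 119.1 close regions on average and at most 164 in 1000 placements (permutation p = 0.001, the smallest possible), which argues against uneven density at the 1 Mb scale as the whole explanation. To test whether single enriched stretches were split into several calls, regions less than 2000 bp apart were joined. Of the 675 that remained, 140 were close to another, against 94.8 on average and at most 134 in random placements (permutation p = 0.001). Joining lowers the number of close regions by construction, so its fall says nothing about splitting, but the number that remained argues against splitting within 2000 bp as the whole explanation. Gene spacing and the clustering of promoters were not examined and stay open, and no biological explanation was tested.

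The concentration of autosomal regions in chromosome centres was tested against 3 technical explanations. After joining regions less than 10000 bp apart, so that a group counts once, the central share was 62.8% with a lower 95% bound of 58.3%. In the better-ranked 50% of the regions the lower bound was 59.4%, which argues against weak calls near the threshold as the cause. With any 1 autosome left out, the lower bound was at least 56.7%, so no single autosome carries the pattern. Mappability, repeat content and gene density differ along worm chromosomes and were not examined, so they stay open, and no biological explanation was tested.

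The series-wide list lacked 4 of the 7 best-ranked regions. A candidate explanation is that their q values fell below the smallest number that double precision holds with full digits (−log10 of 308) and were dropped. Among the 50 listed regions nearest in strength the series-wide −log10 q was 0.63 to 1.48 times the sum of the replicates' values. If the lists share a scale, this puts the chromosome IV region at 349 or more and the III region at 312 or more. V would lie between 281 and 660 and X between 209 and 492. The 1.48 behind these upper values came from 1 region, chromosome V 6220862 to 6230086. That region held 2 peaks of each replicate, and only the lower q of each replicate entered the sum, so its ratio is inflated. Numbers somewhat below the limit can still be stored with fewer digits, so the 312 of the III region does not settle its case. The explanation stays open for the 4 together. For X the values lean against it: 3 stronger regions were listed, at 242 to 264, and the ratios of the 10 nearest regions put X between 216 and 286 and V between 290 and 385. The chromosome I region at 15063998 would reach at most 248 by the ratios of the 50 regions nearest to it, under the limit, which argues against this explanation there. The 248 rests on chromosome II 10541928 to 10547310, which has the same series-wide value, 212, as its neighbour at 10547394 to 10552971. The weak chromosome III region lies 194 bp from its absent strong neighbour, where peaks of the series-wide list lie 201 bp or more apart. The 194 bp is a gap between merged intervals of both replicates, not between called peaks. Some listed consensus regions with gaps under 201 bp shared a series-wide value and others had different ones. The gap therefore cannot tell whether both absent regions were joined into 1 interval and lost together. Removal by the authors and biological explanations were not tested.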
